A study of Mus musculus with 8 samples.

How the data were processed

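Gene expression was measured in mouse cells on 8 two-colour Agilent arrays with probes of 60 bases. Per the labels, each array carried total RNA of 1 sample in Cy3 (green) against a common reference in Cy5 (red), and no dye swap was made. The reference was made of 2 parts of RNA pooled from 11 cultured mouse cell lines and 1 part of RNA from 129 embryonic stem cells. The samples were embryonic stem cells (ESC) and trophectoderm cells (TE), each of wild-type genotype or without both B-type lamin genes, Lmnb1 and Lmnb2 (called lamin B null here), with 2 arrays in each of the 4 groups. The labels state that 2 independent cell lines were used per genotype, without saying which array belongs to which line, so the arrays of a group were treated as replicates. The labels of the wild-type TE samples disagree with themselves: their title and genotype name the wild type, while the entry for genetic modification names a knockout. Groups follow title and genotype, and the deletion was not checked on any array.

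Per the file headers, the authors scanned the spots with Agilent Feature Extraction 9.5.1.1 under protocol GE2-v5_95_Feb07. The deposited scanner files hold, for each spot and channel, the mean intensity of the spot and the median intensity of its local background on a linear scale. They also hold processed intensity values, which per the file headers were background-subtracted, detrended and dye-normalized (linear and lowess), with substitute values for dim spots, and a log10 ratio of red over green. Per the file headers, further columns flag each spot as 0 or 1 for being well above background, saturated or an outlier, which when averaged over the spots of a probe is a fraction. A deposited table of 25030 features holds values on a log10 scale. How that table was made is not given in the sources used here. Its values followed the mean over all arrays of the log10 reference signal minus each array's own log10 ratio, with a correlation between 0.9998 and 1.000 on the 8 arrays and column medians of 2.27 to 2.33, so its scale and direction were settled from the values and the choice of its features stays unknown.

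Here, normexp background correction with an offset of 50 was applied to the mean spot and median background intensity in limma 3.58.1 under R 4.3.3. Each array was then normalized by loess, with control spots and outlier spots left out, and the ratio was turned to log2 of sample over reference. Spots of a probe were averaged, which concerned 7 of the 42006 probes. A probe was tested if the sample channel was well above background on both arrays of at least 1 group, which held for 27418 probes, and 58 of these with an outlier spot were left out, leaving 27360. On the 8 arrays, between 47.1% and 68.0% of the probes were well above background in the sample channel, no spot was saturated, and the median sample signal lay between 107 and 156 over a median local background of 42 to 47. The number of arrays limits the precision.

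Differences were tested with lmFit and eBayes in limma, with all 8 arrays in a fit of 4 group means that left 4 residual degrees of freedom, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Where counts at an unadjusted p under 0.05 are given, chance alone would place a share of 0.05 of the tested probes there. The comparisons were lamin B null against wild type within ESC and within TE, the difference of these effects between TE and ESC, TE against ESC within each genotype, and a genotype effect common to both cell types from a model with genotype and cell type as terms. Where a probe was not well above background on every array of one group, its change was given as at least N-fold, from the mean of the brighter group in the sample channel (after loess and Aquantile) over the mean of the dimmer group, with each array of the dimmer group set to the higher of its own value and the lowest signal among probes well above background. All samples were in the same dye, so a constant dye bias of a probe is shared by both groups, while without dye swaps a dye bias that changes with intensity was not tested. As the bounds are taken in the sample channel they can exceed the fold fitted to the ratios. On lamin B null TE replicate 2 the lowest signal among probes well above background was 4.00 on the log2 scale. It was 6.32 to 7.21 on the other arrays, so it hardly limits the fold in that group. Folds of probes dim in lamin B null TE are therefore given in the sample channel and not as a bound. The fits were tested on simulated data with the spread of the 27360 probes and 200 changed probes in each of 10 runs. The noise was independent between arrays with 1 spread per probe for all 4 groups. It thus carried no deviation shared between arrays and no difference in spread between groups. False calls made up 6.29% of the calls for genotype within ESC and 4.52% for the common effect. For the genotype comparison within ESC, the share recovered was 1.00% of the probes changed 1.41-fold, 39.0% of those changed 2-fold and 91.6% of those changed 4-fold. For the genotype effect common to both cell types, it was 14.4% at 1.41-fold, 81.4% at 2-fold and 96.4% at 4-fold.

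All ESC arrays lay on 1 slide and all TE arrays on another, so slide and cell type cannot be told apart, except through the reference RNA that every array shared. The genotype comparisons lay within a slide. In the reference channel alone, 355 probes differed between the slides in limma at an adjusted p under 0.05, of which 80 by at least 2-fold. In the sample channel alone, 17144 differed, of which 9146 by at least 2-fold.

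Arrays with the same replicate number in the 2 genotypes deviated together. The difference between replicates 1 and 2 correlated across probes between wild type and lamin B null, with r = 0.64 in ESC and r = 0.52 in TE. Same-numbered ESC and TE arrays did not, with r = 0.08 in wild type and r = -0.03 in lamin B null. Over the 4 pairs within a cell type the numbers were taken to pair the arrays, from the data and not from the labels, and the fit with the replicate number as a block was run beside the unblocked one. Counts and intervals are from the unblocked fit unless the block is named.

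The probes carry an identifier and a sequence, and 0 of them carry a gene name in the files used here. The fixed gene lists, the check of the deleted genes Lmnb1 and Lmnb2, and the rule of 1 probe per gene were therefore not used, and each probe was tested on its own. For the same reason no genomic position was given, and in each comparison at most 2 probes are named per direction. The naming rule, fixed with the groups, tests and alternatives before the data were examined, takes the largest change among called probes that were well above background on all arrays compared and whose groups did not overlap, and the largest change among called probes that were not well above background in one group. Where fewer than 5 probes passed, it takes those with the smallest p. The number named was reduced once the probes turned out to have no gene names. The alternatives tried were the processed signals, no background subtraction, median centring in place of loess, Aquantile between arrays, the sample channel alone, the deposited table, other filters on dim probes, other thresholds, a trended robust variance, array weights, only the arrays compared, the replicate block, and each array left out in turn.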

Results

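The study asked what B-type lamins, proteins of the lamina under the inner nuclear membrane, do for gene expression in embryonic stem cells and in cells that leave the stem cell state. The ESC lines were derived from blastocysts of intercrossed mice heterozygous for Lmnb1 and Lmnb2 and carried Cdx2, a transcription factor of the trophectoderm lineage, as a fusion that tamoxifen switches on. TE cells were made from these lines by 2 days with tamoxifen in 30% TS medium and 6 further days in undiluted TS medium. Each combination of cell type and genotype was measured on 2 arrays.

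Cell type set most of the differences between the arrays. It took 87.7% of the sum of squares over the 27360 tested probes, genotype took 2.02%, their interaction 1.36%, and the spread between replicates 8.89% over 4 degrees of freedom, or 2.22% for each. Log2 ratios of the ESC arrays correlated across probes between 0.95 and 0.97 with each other, and those of ESC with TE arrays between 0.14 and 0.22. Among the TE arrays, wild-type replicate 1 stood apart, with correlations of 0.81 to 0.91 to the other 3, which correlated between 0.94 and 0.97 among themselves. The difference between the 2 replicates had an SD of 0.24 in wild-type ESC, 0.29 in lamin B null ESC, 0.63 in wild-type TE and 0.38 in lamin B null TE on the log2 scale, across probes, which are not independent replicates.

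TE and ESC differed in 55.0% of the tested probes of wild-type cells. In limma, 15046 probes passed an adjusted p of 0.05, with 8065 higher in TE and 6981 lower, and 9039 of them changed at least 2-fold. At least 4-fold changes went up in 1896 probes and down in 1325. Probe Z00025177-1 (sequence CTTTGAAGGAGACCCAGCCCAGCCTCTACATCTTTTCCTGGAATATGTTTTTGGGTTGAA) rose from a mean log2 ratio of -4.51 ± 1.08 (SD, n = 2) in ESC to 3.12 ± 1.22 (SD, n = 2) in TE. That rise of 7.62 (SE 0.78) had an adjusted p of 0.000398 in limma. Probe Z00063643-1 (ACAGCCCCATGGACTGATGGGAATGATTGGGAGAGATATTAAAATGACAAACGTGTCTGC) fell by 7.46 (SE 0.57), from 2.41 ± 0.18 (SD, n = 2) to -5.05 ± 1.40 (SD, n = 2), with an adjusted p of 0.000149 in limma.

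Some probes of wild-type cells were well above background in one cell type only. Probe Z00010007-1 (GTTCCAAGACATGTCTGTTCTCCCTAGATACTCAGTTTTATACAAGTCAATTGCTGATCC) was not well above background on either wild-type ESC array and was at least 97.7-fold higher in TE (limma adjusted p = 0.000512). Probe Z00027110-1 (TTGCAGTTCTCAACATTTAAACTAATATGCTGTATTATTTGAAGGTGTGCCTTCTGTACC) was not well above background on either wild-type TE array and was at least 18.1-fold higher in ESC (limma adjusted p = 0.000826). Over both genotypes, 1022 tested probes were well above background on all 4 TE arrays and on no ESC array, and 165 on all 4 ESC arrays and on no TE array. The ESC arrays of wild-type cells had 19764 and 23906 probes well above background, against 25408 to 28556 on the other 6 arrays. With median centring in place of loess 8468 probes passed and the share higher in TE was 38.1% in place of 53.6%, and the deposited values, which held 17083 of the tested probes, gave 9884.

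Lamin B null cells also changed broadly from ESC to TE. In limma, 14309 probes passed the threshold, 7572 higher in TE and 6737 lower, and 8742 changed at least 2-fold. At least 4-fold changes went up in 1875 probes and down in 1145. Probe Z00019741-1 (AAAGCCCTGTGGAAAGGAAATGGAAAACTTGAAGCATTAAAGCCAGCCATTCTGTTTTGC) rose by 8.06 (SE 0.42), from -4.18 ± 0.23 (SD, n = 2) in ESC to 3.88 ± 0.63 (SD, n = 2) in TE, with an adjusted p of 5.80e-05 in limma. Probe Z00038583-1 (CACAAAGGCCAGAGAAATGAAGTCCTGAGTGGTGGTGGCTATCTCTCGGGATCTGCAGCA) fell by 7.61 (SE 0.43), from 1.58 ± 0.11 (SD, n = 2) to -6.03 ± 0.39 (SD, n = 2), with an adjusted p of 7.12e-05 in limma. Probe Z00024966-1 (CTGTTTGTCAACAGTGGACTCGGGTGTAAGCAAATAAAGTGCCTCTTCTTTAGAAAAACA), not well above background in lamin B null ESC, was at least 70.9-fold higher in TE (limma adjusted p = 7.01e-05). Probe Z00027126-1 (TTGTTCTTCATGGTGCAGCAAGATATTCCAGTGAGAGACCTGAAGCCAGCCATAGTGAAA), not well above background in lamin B null TE, was 15.5-fold higher in ESC in the sample channel alone, while its log2 ratio to the reference fell by 3.82 (SE 0.67, limma adjusted p = 0.00359). With median centring in place of loess 7788 probes passed and the share higher in TE was 34.9% in place of 52.9%.

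The change from ESC to TE was close to parallel in the 2 genotypes. Of the 15046 probes called in wild type and the 14309 called in lamin B null, 12975 were called in both, and 12974 of these changed in the same direction, 6829 higher in TE and 6145 lower. Independent lists of these sizes would share 2232 higher and 1719 lower. The log2 changes correlated with r = 0.97 across probes, and a total least squares line of lamin B null on wild type had a slope of 0.97. A further 2071 probes were called in wild type only and 1334 in lamin B null only, and 97.6% of these had the same sign in the other genotype. The 1 probe called in opposite directions, Z00070615-1, named after its values were seen, rose by 0.56 (SE 0.14) in wild type with a limma adjusted p of 0.0164. It fell by 0.80 (SE 0.14) in lamin B null with a limma adjusted p of 0.00402, and the difference of the effects did not pass (adjusted p = 0.842).

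**Figure D1:**
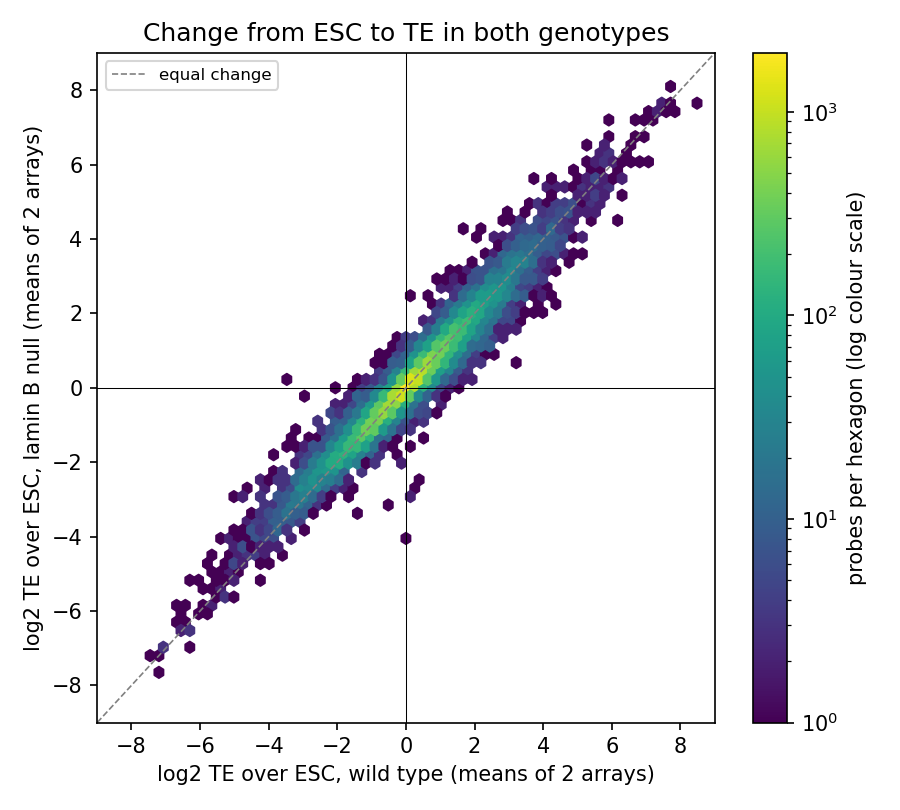
Log2 change from ESC to TE for the 27360 tested probes, with wild-type cells on the horizontal axis and lamin B null cells on the vertical axis, each from means of 2 arrays; colour gives the number of probes per hexagon on a log scale. The probes lie along the dashed line of equal change (r = 0.97 across probes).

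Between lamin B null and wild-type ESC, 34 of 27360 probes passed the threshold in limma, 16 higher and 18 lower in lamin B null cells, all of them by at least 2-fold, with 12 at least 4-fold higher and 14 at least 4-fold lower. On simulated data, with independent noise of the same spread in all groups, this comparison recovered 1.00% of the probes changed 1.41-fold and 39.0% of those changed 2-fold. Probe Z00076280-1 (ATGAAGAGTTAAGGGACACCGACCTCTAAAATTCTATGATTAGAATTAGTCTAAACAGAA) was not well above background on either wild-type ESC array and was at least 76.5-fold higher in lamin B null ESC, with an adjusted p of 0.00326 in limma. Probe Z00017768-1 (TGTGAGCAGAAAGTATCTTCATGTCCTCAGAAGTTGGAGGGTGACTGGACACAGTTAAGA), well above background on all arrays, rose by 3.03 (SE 0.17), from -2.18 ± 0.08 (SD, n = 2) in wild type to 0.85 ± 0.03 (SD, n = 2), with a limma adjusted p of 0.00524. Probe Z00056538-1 (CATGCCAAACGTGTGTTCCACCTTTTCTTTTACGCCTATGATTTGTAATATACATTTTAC) fell by 3.60 (SE 0.19), from 0.48 ± 0.02 (SD, n = 2) to -3.12 ± 0.31 (SD, n = 2), with a limma adjusted p of 0.00524. Probe Z00070209-1 (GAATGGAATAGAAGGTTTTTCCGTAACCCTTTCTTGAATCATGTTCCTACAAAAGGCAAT) was not well above background in lamin B null ESC and was at least 7.50-fold higher in wild type (limma adjusted p = 0.00647).

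Of the 34 called probes, 18 were well above background on all 4 ESC arrays, 5 were not well above background on either wild-type array and 5 on neither lamin B null array. At an unadjusted p under 0.05 there were 924 probes, fewer than chance alone would give, and 1727 with the replicate block, more than chance would give. The 95% interval of the change lay within 2-fold either way for 86.3% of the tested probes. That interval takes 1 spread per probe for all 4 groups, which may be too wide for ESC, where replicates differed less than in TE. In limma the count was 0 without lamin B null replicate 1, wild-type replicate 1 or wild-type replicate 2 (703, 482 and 531 at an unadjusted p under 0.05), 3 without lamin B null replicate 2, and 22 without either lamin B null TE array, where a lone array is assumed to vary like those of the other groups. Median centring left 14 probes, of which 14.3% were higher in place of 47.1%, the deposited values 4 (of 17083 probes tested) and a filter to probes above background on all 8 arrays 12, while array weights gave 117.

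In TE, 6 probes passed the threshold between the genotypes in limma, 1 higher and 5 lower in lamin B null cells, all by at least 4-fold. Probe Z00076280-1, which was also called in ESC, rose by 3.51 (SE 0.27), from -3.32 ± 0.18 (SD, n = 2) in wild-type TE to 0.19 ± 0.49 (SD, n = 2), with a limma adjusted p of 0.0367, or 0.109 with the replicate block. Probe Z00036741-1 (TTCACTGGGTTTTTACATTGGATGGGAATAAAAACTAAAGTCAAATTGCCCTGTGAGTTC) fell by 3.19 (SE 0.22), from 3.43 ± 0.19 (SD, n = 2) to 0.24 ± 0.18 (SD, n = 2), with a limma adjusted p of 0.0273. Probe Z00062996-1 (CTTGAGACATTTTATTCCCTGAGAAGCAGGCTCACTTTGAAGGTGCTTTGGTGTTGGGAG) was not well above background in lamin B null TE and was 4.79-fold higher in wild type in the sample channel alone, while its log2 ratio to the reference fell by 2.25 (SE 0.12, limma adjusted p = 0.00981). With the replicate block 5 probes passed in TE, of which 3 were among the 6.

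At an unadjusted p under 0.05, 957 probes differed between the genotypes in TE, fewer than chance alone would give. With the replicate block it was 2533, more than chance would give. The block fit also took 1 spread per probe for both cell types. The genotype difference in TE had an SD of 0.274 across probes. On the same scale, the replicate difference not shared by the 2 genotypes had an SD of 0.272 in TE and 0.115 in ESC. That spread may thus be too small for TE, so the 2533 do not show a broad genotype effect there. The 95% interval lay within 2-fold for 83.1%. That interval takes 1 spread per probe for all 4 groups, which may be too narrow for TE, where replicates differed more than in ESC. It also counts the deviation shared by same-numbered arrays, which widens it. Whether it is too narrow or too wide for TE is thus not settled. The wild-type TE arrays differed from each other by over 2-fold in 2641 probes. The genotype count in TE was 1187 without wild-type TE replicate 2, when only the array that stood apart was left in that group, 5 without wild-type TE replicate 1 (3 of them among the 6), 0 without lamin B null TE replicate 1 (1334 at an unadjusted p under 0.05), 2 without lamin B null TE replicate 2, 1 without any one ESC array, and 1 without both TE arrays of replicate 1, a choice made after seeing the data. In limma it was 0 with median centring, with the deposited values, with probes above background on all 8 arrays or with the TE arrays alone (283, 713, 638 and 399 at an unadjusted p under 0.05), 10 with the sample channel alone (30.0% higher in place of 16.7%), 39 with the processed signals (53.8% higher) and 21 without background subtraction.

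The genotype differences of ESC recurred in TE. All 6 probes called in TE were among the 34 called in ESC, with the same sign, 1 higher and 5 lower. For the lower probes alone, independent lists of these sizes would share 0.00329. Of the 34, 33 had the same sign in TE and 27 also had an unadjusted p under 0.05 there. No array enters the group means of both comparisons, while the spread of a probe came from all 8 arrays in both. A low spread can thus place a probe on both lists, so the numbers for independent lists may be too low. It does not set the sign. TE cells were, however, made from the ESC lines, of which there were 2 per genotype. A difference between lines that is not due to the deletion can thus recur in TE with the same sign. The recurrence is therefore not an independent replication of a genotype effect. At an unadjusted p under 0.01 in both cell types, 41 probes were higher in both (0.483 for independent lists), 38 lower in both (0.799) and 1 went opposite ways (1.28). Over all 27360 probes the genotype effects correlated with r = 0.20, across probes.

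**Figure D2:**
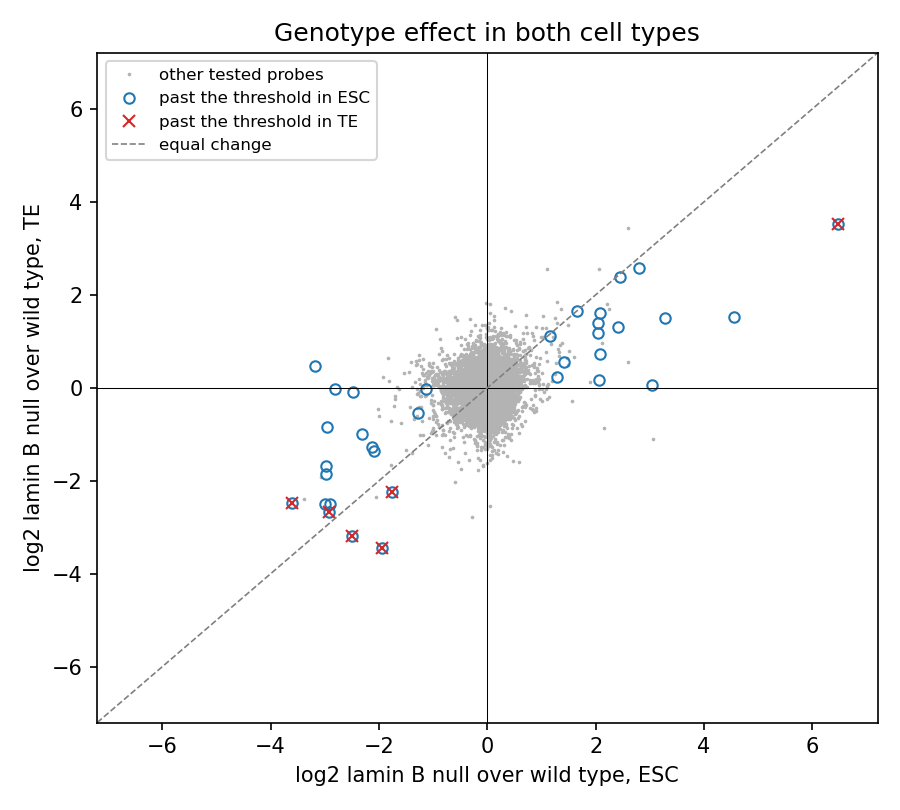
Log2 change of lamin B null over wild type in ESC (horizontal axis) and in TE (vertical axis), each from 2 arrays against 2, for the 27360 tested probes; circles mark the 34 probes past the threshold in ESC and crosses the 6 past it in TE. All 6 crosses fall on circles, and 33 of the 34 circles have the same sign on both axes.

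No probe passed the test of the difference between the genotype effects of TE and ESC in limma, with a smallest adjusted p of 0.132. At an unadjusted p under 0.05 were 596 probes, fewer than chance alone would give. Probe Z00032719-1 had the smallest p, with an effect 3.65 (SE 0.26) higher in TE than in ESC, where lamin B null cells had -1.06 ± 0.01 (SD, n = 2) against 2.11 ± 0.21 (SD, n = 2) in wild type. In TE this probe had -0.87 ± 0.33 (SD, n = 2) against -1.34 ± 0.04 (SD, n = 2), and was well above background on only 1 TE array of each genotype. Probe Z00017768-1, which rose in lamin B null ESC, had -2.02 ± 0.08 (SD, n = 2) in lamin B null TE against -2.08 ± 0.33 (SD, n = 2) in wild-type TE, and its difference of effects was -2.97 (SE 0.24) with a limma adjusted p of 0.149. With the replicate block 1747 probes had an unadjusted p under 0.05, more than chance would give. In that fit 1 probe passed, Z00055038-1, named after its values were seen, with a difference of -4.14 (SE 0.14) and a limma adjusted p of 0.0420. The 95% interval of the difference of effects lay within 2-fold for 67.8% of the probes. The count was 1 with the processed signals or without background subtraction, 104 without wild-type TE replicate 2, 1 without both TE arrays of replicate 1, and 0 without any other single array (286 to 1257 at an unadjusted p under 0.05).

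**Figure D3:**
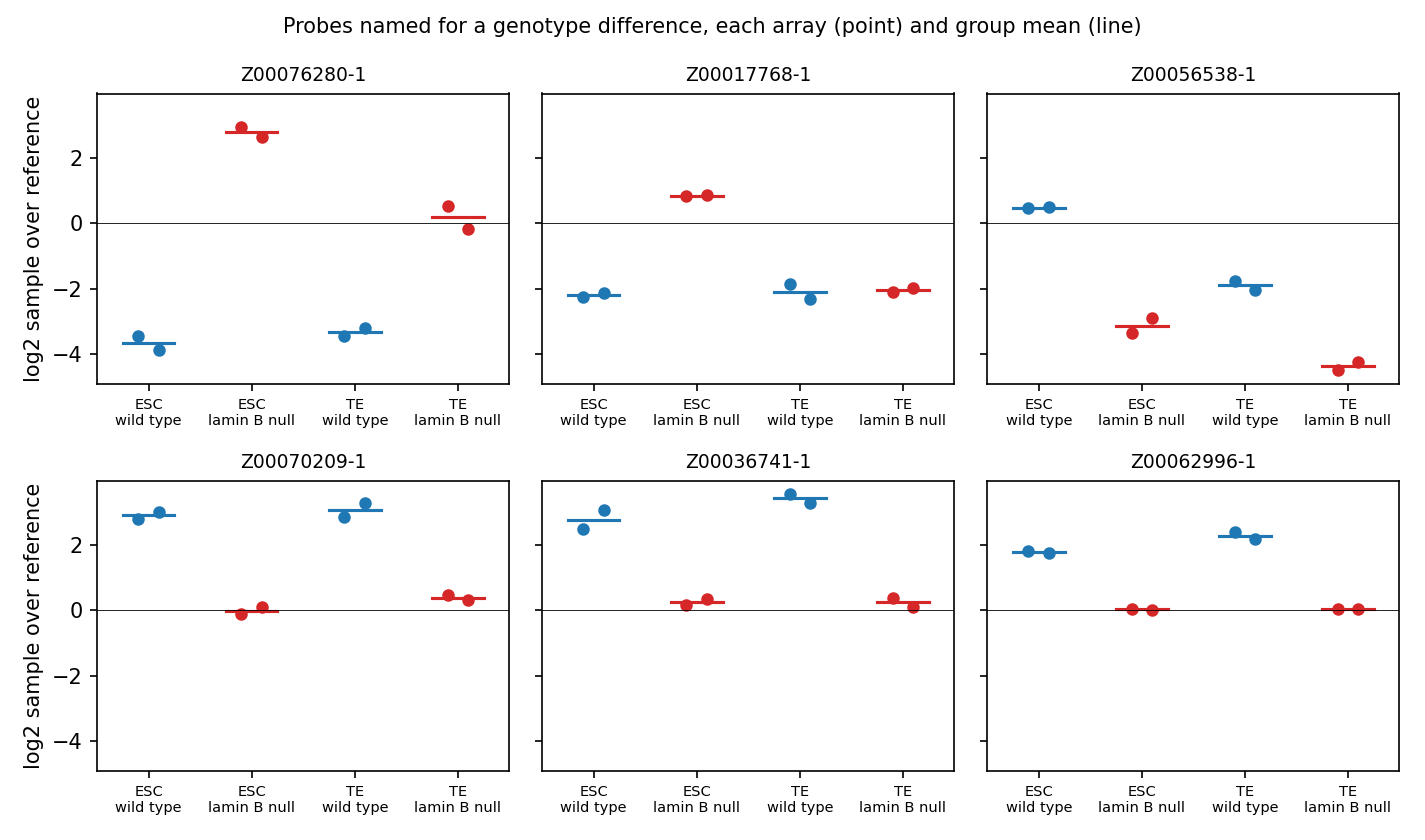
Log2 ratio of sample over reference on each array (points) with the mean of the 2 arrays (lines) for 6 probes named for a genotype difference, wild type in blue and lamin B null in red. Z00017768-1 differs between the genotypes in ESC (-2.18 against 0.85) and has -2.08 and -2.02 in TE, while Z00036741-1 is lower in lamin B null cells of both cell types.

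A genotype effect common to both cell types was called for 39 probes in limma, 19 higher and 20 lower in lamin B null cells, and 33 of them by at least 2-fold. The fit took the 4 arrays of a genotype as independent, while ESC and TE arrays came from the same 2 lines per genotype. Its p-values and intervals may thus understate the spread between lines. Probe Z00071747-1 (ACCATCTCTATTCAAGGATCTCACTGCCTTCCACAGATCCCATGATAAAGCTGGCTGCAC) rose by 2.68 (SE 0.17), with a limma adjusted p of 0.00283, and was higher on each of the 4 lamin B null arrays than on any wild-type array. Probe Z00012423-1 (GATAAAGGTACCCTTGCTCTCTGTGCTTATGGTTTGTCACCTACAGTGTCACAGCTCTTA) rose by 2.42 (SE 0.16; limma adjusted p = 0.00300). Probe Z00056538-1 fell by 3.03 (SE 0.24; limma adjusted p = 0.00573), and probe Z00075211-1 (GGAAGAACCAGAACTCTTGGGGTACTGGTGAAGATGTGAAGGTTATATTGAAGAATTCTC) fell by 2.88 (SE 0.33; limma adjusted p = 0.0317, or 0.0505 with the replicate block). All 39 had the same sign in ESC and TE, and 19 were also among the 34 called in ESC, on arrays that enter both fits.

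In the test of a common genotype effect 1270 probes had an unadjusted p under 0.05, fewer than chance alone would give, and the 95% interval lay within 2-fold for 94.5%. With the replicate block 23 probes passed, of which 21 were among the 39, and 2140 had an unadjusted p under 0.05, more than chance would give. The count was 14 with median centring (7.10% higher in place of 48.7%), 17 with the deposited values (of 17083 probes tested), 70 with the processed signals and 95 with array weights, and with the sample channel alone 34.1% of the called probes were higher. The count lay between 12 and 24 without any one of the 4 ESC arrays or either lamin B null TE array, being 12 without lamin B null ESC replicate 2, and it was 25 without both TE arrays of replicate 1, a choice made after seeing the data.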

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

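Leaving out both TE arrays of replicate 1 was chosen after seeing the data. All other alternatives were set before. Each count of called probes is compared with the reported one, and where it moved by over 1.5 times the cause was not tested, except where fewer probes or arrays enter. The deposited values held 17083 of the tested probes. Without the filter on dim probes the count for genotype in ESC was 33. For genotype in ESC (34), median centring gave 14, the deposited values 4, all 8 arrays above background 12 and array weights 117, and single arrays left out 0 to 38. For genotype in TE (6), the processed signals gave 39, no background subtraction 21, the sample channel alone 10, an adjusted p under 0.10 21, the trended robust variance 1, array weights 2, and both TE arrays of replicate 1 left out 1. Median centring, the deposited values, the filter to all 8 arrays and the TE arrays alone gave 0 in limma, with 283, 713, 638 and 399 probes at an unadjusted p under 0.05. Single arrays left out gave 0 to 1187. For the difference of genotype effects (0 in limma, 596 at an unadjusted p under 0.05), the processed signals, no background subtraction, the replicate block and both TE arrays of replicate 1 left out gave 1 each, and single arrays left out 0 to 104.

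For TE against ESC in wild type (15046), median centring gave 8468, the deposited values 9884, a 2-fold minimum 9039 and single arrays left out 10668 to 15887. In lamin B null (14309), median centring gave 7788, a 2-fold minimum 8742 and single arrays left out 10595 to 16524. For the common genotype effect (39), the processed signals gave 70, median centring 14, the deposited values 17, array weights 95, the replicate block 23, both TE arrays of replicate 1 left out 25, and single arrays left out 12 to 49. The replicate block gave 30 in ESC, 5 in TE, 13909 in wild-type TE against ESC and 13332 in lamin B null, each within 1.5 times, and 24 of the 30 and 3 of the 5 were among the unblocked calls. Same-numbered ESC and TE arrays share only a number. The median log2 change of all probes moved by over 0.1 with the processed signals, by 0.14 for the difference of genotype effects and 0.10 for TE against ESC in lamin B null, with median centring, by -0.18 for TE against ESC in wild type and -0.13 in lamin B null, and with the sample channel alone, by -0.11 in lamin B null. The probes taken by the naming rule, of which only a part is named above, were followed over 767 refits. No direction turned, 661 kept their side of the threshold, 101 lost it and 5 gained it. In many of these refits only the spread, the threshold, the probe filter or the arrays of other groups changed. The log2 change was then the same and its direction could not turn. The 4 probes the rule took for genotype in TE lost their side of the threshold in 53 of 87 refits and the 8 for genotype in ESC in 37 of 168. The 4 for the common effect lost it in 11 of 88, and the 8 of each TE against ESC comparison in none. The mean over probes of a gene and the gene lists were not run, for want of gene names, nor was the slide as a block, which coincides with cell type.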

Other observations

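The tests of GC content and brightness, of the line number, of shared handling, of ESC RNA and of compression, and the forms of the strain variant test given here, were chosen only after the result was seen. The form set before asked for at least 1 probe with an unadjusted interval, which 22 probes can give by chance.

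The probes called by genotype in ESC differed in how far the difference carried over to TE, with a median ratio of the TE to the ESC effect of 0.571 over the 34 probes. Choosing probes by their ESC effect tends to lower this ratio, and a dim TE signal, as in 12 of them, can lower it too. It therefore does not show a weaker genotype effect in TE. Z00031212-1, named after its values were seen, had -2.81 (SE 0.21) in ESC and -0.02 (SE 0.21) in TE. A different base under the probe, as a mixed strain background could leave near the deleted genes, would alter binding alike in both cell types. Of the 22 called probes well above background on all 4 TE arrays, 4 had a TE effect short of 0.5 of the ESC effect in limma, with the spread of all 4 groups and an interval adjusted for the 22 (6 unadjusted, where 0.55 would by chance). This argues against such a base for these 4 only if their TE signal came from the transcript itself, which was not tested. Among them, Z00017768-1 had -2.08 and -2.02 in TE, near its lower ESC level of -2.18. Z00026894-1 had 1.06 and 0.97 in TE, near its higher ESC level of 0.98. With no spread taken under the median of all probes 3 passed, and with the spread of each cell type taken alone 0 (5 unadjusted, and the same 4 adjusted by Benjamini and Hochberg). Adjusted over the 22 alone, 13 differed at all, while over all 27360 probes no difference of the effects passed (596 at an unadjusted p under 0.05). The 22 were chosen by their ESC effect, which is also a part of each of these tests. Such a choice can raise the numbers, so the 13 are not a valid count and 0.55 may be too low. For the other 30 called probes, of which 12 were not well above background on every TE array, a strain variant and a genotype effect on expression cannot be told apart, since their intervals did not exclude 0.5 of the ESC effect or their TE signal was dim.

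Chance was tested for the common genotype effect by regrouping the 8 arrays into 4 and 4. Of 34 regroupings that could be fitted, the real one included, 1 gave as many called probes as genotype, namely genotype itself with 39, and the highest of the others gave 0. Of the 34, 18 held 2 ESC arrays on each side and 8 parted all 4 pairs of same-numbered arrays, as genotype does, and each of these numbers is too few for a share under 0.05. Single arrays were regrouped, although ESC and TE arrays of a genotype came from the same 2 lines. Differences between lines that are not due to the deletion were therefore not tested.

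Same-numbered arrays of the 2 genotypes deviated together within a cell type. Once a joint trend with GC content and brightness was removed, the correlation of the replicate differences was still at least 0.515 (0.650 in the other cell type), and once a smooth surface over the array was removed it was at least 0.517, so neither is likely to be the cause. The sample channel alone gave at least 0.491, which argues against the reference channel, and the higher of the correlations between ESC and TE replicates was 0.0787, which argues against a line number carried from ESC to TE. That samples of a number were grown or labelled together stays open at a correlation of 0.516, since growth and labelling cannot be told apart in these files. No biological explanation was tested.

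Wild-type TE replicate 1 stood apart from the other 3 TE arrays, and the genotype count in TE was 1187 without wild-type TE replicate 2 and 5 without replicate 1, against 6 with both. Compressed log ratios are an unlikely cause of the whole difference, since the residual SD of this array on each other TE array was at least 0.409 once a curved trend joint with brightness was removed, against at most 0.379 among the other 3, and its rank correlations with them were 0.771 to 0.877 against 0.926 to 0.968, while compression in part stays open. The share of ESC RNA that best fitted the difference between the wild-type TE arrays, 5%, explained 4.24% of its sum of squares (bootstrap 3.75% to 5.12%), which argues against undifferentiated ESC RNA as the whole difference. That share would change the 103 probes at least 16-fold lower in TE by a median of 1.40 and the 257 at least 16-fold higher by -0.07, where replicate 1 differed from replicate 2 by 0.47 (bootstrap 0.37 to 0.60) and -0.37 (bootstrap -0.49 to -0.21). A smaller part of ESC RNA and an incomplete differentiation of that culture stay open and were not tested apart. Of 1234 probes over 2-fold apart that were also called between TE and ESC in lamin B null, 27.1% (95% interval 24.7% to 29.7%) differed away from the ESC level. This interval and the bootstraps are over probes, which are not independent replicates, and give no spread between arrays or cultures. The difference was partly shared with lamin B null TE. The rest of replicate 1 after a linear trend on replicate 2 correlated with the lamin B null replicate difference (r = 0.68). Before the trend was removed, r was 0.52 across probes. What set this array apart was thus in part not a trait of its culture alone. With each ESC array, wild-type TE replicate 1 had the lowest correlation of all TE arrays (0.142 to 0.184). Other differences of this array can also lower that correlation, so it does not decide the question.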
